A study of Homo sapiens with 4 samples.

How the data were processed

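Per the labels, total RNA of MKN-45 and MKN-45-P cells was labelled with Cy3 and hybridised to 1 array per sample, with 2 samples of each line. Per the file headers, the authors' arrays are of the Agilent-014850 design, read in 1 channel by Agilent Feature Extraction 9.5.1.1 with the protocol GE1-v5_95_Feb07. Agilent Feature Extraction 9.5 is also named in the submitters' processing notes. The deposited values used are the processed intensity of each spot, which per the file headers is background-subtracted and detrended within the array, with surrogate values for dim spots, and is not normalized between arrays. The deposited raw mean intensity and median local background intensity of each spot were used in 1 alternative. The deposited value table of the series held the same processed intensity as the scanner output for every spot. All 4 arrays lie on 1 slide and were scanned on 1 day, so neither is a batch.

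Of 41000 probes, 264 were printed 10 times and the others once. Control spots and the outlier spots marked by Feature Extraction (672, 116, 169 and 187 over MKN-45 replicates 1 and 2 and MKN-45-P replicates 1 and 2) were left out, and spots of 1 probe were averaged on the log2 scale. Each array's log2 processed intensity had its own 75th percentile subtracted. A probe was tested when Feature Extraction marked it well above background on both arrays of at least 1 line, which left 22079 probes. On the 4 arrays 19540, 23410, 22203 and 23670 probes were well above background. The number of arrays limits the precision. Spots of a repeated probe varied on the 4 arrays by a median CV of 5.93%, 2.98%, 3.56% and 2.67%. The 7 spike-in controls well above background on all arrays were higher in MKN-45-P by a median of 0.09 on the log2 scale.

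Probes were named through a table of RefSeq genes of the GRCh38.p14 assembly, used only for names: 23434 probes matched by accession without its version, 3360 by symbol or by an older symbol of a single gene, and 14206 had no symbol and were counted as probes only. Positions are those of the array's design, which per the file headers uses the hg17 build. A gene with several tested probes is given by its brightest. Of 1100 called genes with several tested probes, 23 had another probe called in the opposite direction.

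Lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual degrees of freedom, a prior worth 6.86), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. SDs are between the 2 arrays of a line and SEs come from the fit. The labels do not say whether the replicates of a line were separate cultures, a point not given in the sources used here, so p-values measure the spread between these samples, which may be technical. Where a gene was not well above background on either array of 1 line, the fold is a lower bound. It sets the mean of the brighter line against the dimmer line's mean of, per array, the higher of the probe's own level and the lowest level of any probe well above background.

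Before the data were examined, 36 gene lists with 1181 genes were fixed, of which 1168 are on the array. Lists with at least 5 tested genes, 35 of them, were tested with camera at its preset correlation of 0.01 between genes, adjusted over the lists. No list was called with a correlation estimated for each list, an estimate that rests on 2 residual degrees of freedom. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within a list.

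The rule for named genes was fixed at the same time. It takes the 12 genes with the largest rise and the 12 with the largest fall among called genes well above background and unsaturated on all 4 arrays with the lines not overlapping. It adds the 6 per direction with the largest bound, up to 4 called members of each list by size of change, and MET, ERBB2, CDH1, CD44, MKI67 and GAPDH whatever their change. Transcripts without an established gene name were passed over, and some lists are given with fewer members, in order of size. Some genes that the rule would name are not reported here. Genes chosen after their values were seen are said to be so. After the comparison had been seen, 7 further lists were written, on complement, guanylate-binding proteins and nucleic acid sensors, interferon ligands, interferon receptors and signalling, the constitutive proteasome, kallikreins and alcohol, steroid and conjugating enzymes, and were adjusted among themselves. Chromosome medians were set against random gene lists matched on brightness, and neighbouring genes against shuffled positions, 10000 times each.

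Alternatives were quantile normalization, median centring, normexp on the raw and background intensities with an offset of 50, no filter on dim probes, a filter on all 4 arrays, outlier spots kept, probes with a saturated spot left out, an intensity trend in eBayes, the replicate number as a block, each array left out, the series value table, the mean of all tested probes of a gene, an estimated correlation and fry for the lists. With an array left out, its line's other array was assumed to vary like the other line. The workflow was tested on simulated data with the real probe means and SDs, 21831 probes and 200 of them changed. It recovered 4% of log2 changes of 0.5, 62% of 1, and 100% of 2 and of 4, and called 48 of 21631 unchanged probes. Each size of change was given to 50 probes, so these 48 false calls are a far larger share of all calls than the adjusted p threshold allows. In this simulation the threshold thus did not hold false calls to its stated share, and the same may be true of the real calls.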

Results

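Total RNA from 2 human gastric cancer cell lines was measured on 4 one-colour Agilent whole-genome arrays, 2 of MKN-45 and 2 of MKN-45-P. The labels describe MKN-45-P as a highly metastatic line and MKN-45 as its parent, and the comparison asks which genes differ between them. Both lines were grown in the same medium and lifted with trypsin. The arrays held 41000 probes, and 11740 genes had a probe well above background on both arrays of at least 1 line. Between the MKN-45-P arrays the correlation over probes was 0.996, between the MKN-45 arrays it was 0.970, and across the lines it was 0.921 to 0.942. MKN-45 replicate 1 stood apart. Its 75th percentile of processed intensity was 2167, against 1279.6 in MKN-45 replicate 2 and 1339 and 1435 in MKN-45-P, and the lowest intensity of a probe well above background was 186, against 41.3, 65.5 and 49.6. After scaling, the median log2 difference of MKN-45 replicate 1 from replicate 2 was still -0.255 over 21831 probes. Between the MKN-45-P arrays it was -0.026. Over 191 repeated probes the median SD was 0.197 between the MKN-45 arrays and 0.032 between the MKN-45-P arrays. Part of the spread that the fit uses is thus a shift of a whole array.

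Interferon-induced genes were far higher in MKN-45-P than in MKN-45. IFI27 had a normalized log2 level of 6.13 ± 0.03 (SD, n = 2) in MKN-45-P and of -2.68 ± 0.22 (SD, n = 2) in MKN-45, a log2 fold change of 8.81 ± 0.18 (SE, adjusted p = 4.28e-08). The antiviral GTPase gene MX1 rose by 7.003 ± 0.176 (SE) on the log2 scale, IFIT1, whose protein binds viral RNA, by 6.77 ± 0.21, and IFI6 by 6.06 ± 0.19. IRF7, a transcription factor that drives interferon production, was not well above background on either MKN-45 array. It was at least 181-fold higher in MKN-45-P (adjusted p = 4.28e-08), a lower bound as the MKN-45 level was under what could be measured. Its probe lies on chromosome 11 from 602643 to 602702 in the hg17 build, and a second probe gave a log2 fold change of 4.17. IFIT2 and IFIT3 were at least 75.7-fold and 72.2-fold higher, although the second IFIT2 probe gave a log2 fold change of 2.29.

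Of the 46 tested genes of the interferon response list, 45 rose and 0 fell. The count was 46 adjusted over the list alone, and as low as 12 among 15 other settings of the processing. Across those settings the list's median log2 fold change ranged from 2.53 to 2.86. The remaining member, XAF1, named after its value was seen, had a log2 fold change of 3.88 ± 1.54 (SE, adjusted p = 0.0903). MX2, well above background on only 1 MKN-45 array, rose by about 7.94 ± 0.28 on the log2 scale, and IFI44 was at least 57.1-fold higher. The list's median log2 fold change was 2.81, also with genes under background at their bound, and limma's camera gave an adjusted p of 1.56e-52. The adjusted p was 0.9995 with an estimated correlation, and the unadjusted p was 0.0461. In each of the 46 genes both MKN-45-P arrays lay above both MKN-45 arrays. Of these, 11 were not well above background on either MKN-45 array. The filter let them in only through MKN-45-P, which made their separation likely in advance. The lines did not overlap, in either direction, in 68.5% of all tested genes, and random splits would part them so in 33.3%. Among 27 markers of leukocytes and endothelium, 4 were tested: CD68, a lysosomal protein of macrophages, rose by 1.90 ± 0.18 on the log2 scale, and the lysozyme gene LYZ had a log2 fold change of -1.73 ± 0.18, a call lost without MKN-45-P replicate 1 (adjusted p = 0.0659) or replicate 2 (0.0807). CD14 (0.29 ± 0.21) and CD79A (0.05 ± 0.19) did not pass the test.

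**Figure D1:**
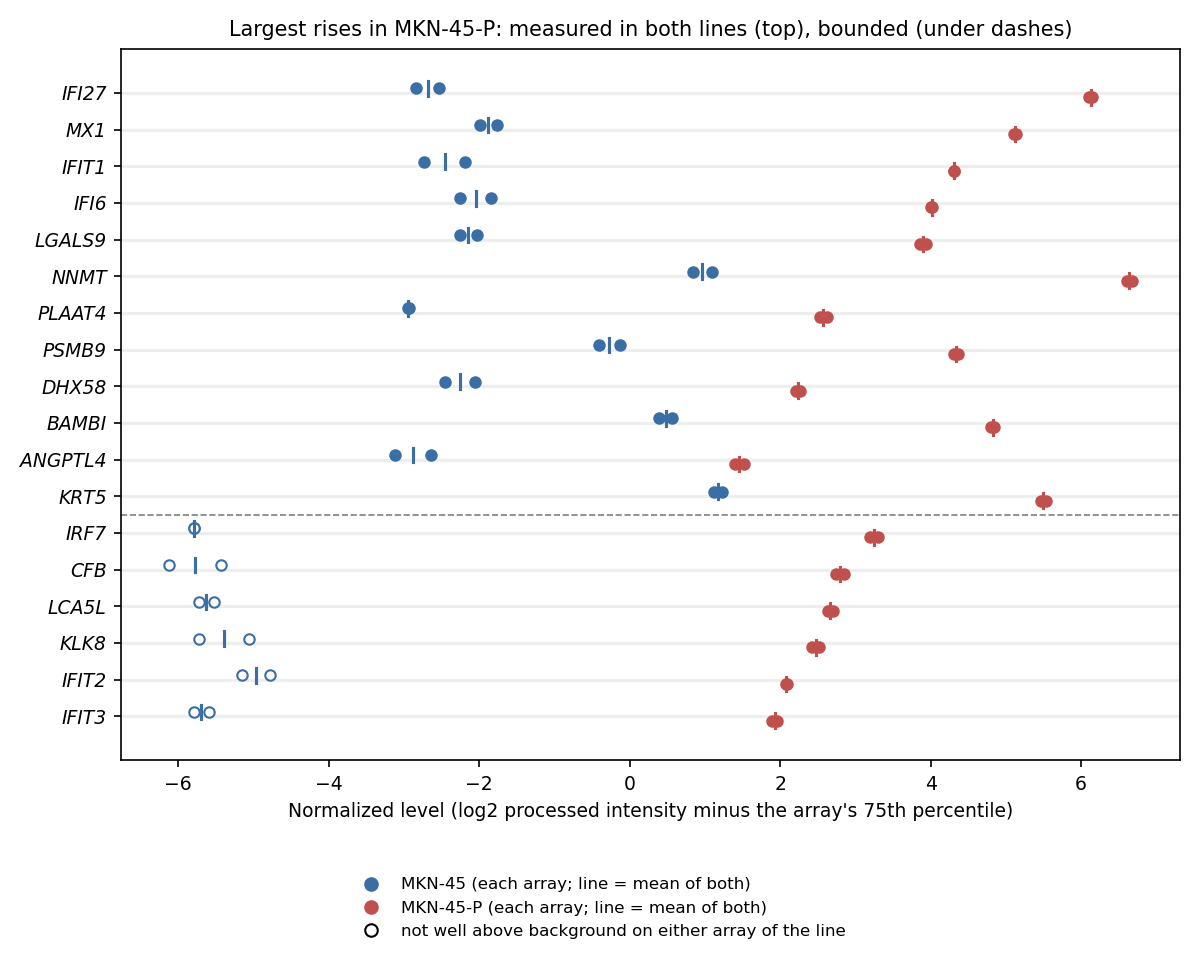
Normalized level of each gene (x axis, log2 processed intensity minus the array's 75th percentile) on the 2 arrays of each line, with a vertical line at each mean. The 12 upper genes were well above background on all 4 arrays; the 6 lower ones were not well above background on either MKN-45 array (open points). For IFI27 the MKN-45-P mean was 6.13 and the MKN-45 mean -2.68.

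Antigen presentation genes rose with them. PSMB9, an interferon-inducible proteasome subunit, rose by 4.61 ± 0.18 (SE) on the log2 scale, the peptide-trimming enzyme ERAP2 by 3.37 ± 0.18 and the peptide transporter TAP1 by 2.81 ± 0.18. HLA-DRA, a class II chain, was at least 2.11-fold higher. Of the 28 tested genes of the list, 22 rose, 1 fell and 5 did not pass, with the same 22 and 1 adjusted over the list alone. The gene that fell, HLA-DMB (log2 fold change -1.30 ± 0.18), was named after its value was seen. Without either MKN-45-P array 13 genes rose and 0 fell. The median log2 fold change was 1.67, or 1.44 with genes under background at their bound. The camera adjusted p was 4.91e-12 (adjusted p = 0.9995 with an estimated correlation). HLA probes can bind transcripts of several HLA genes.

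Other genes with large rises came from several functions. NNMT, which methylates nicotinamide, rose by 5.68 ± 0.18 on the log2 scale, LGALS9, a galectin, by 6.04 ± 0.18, and PLAAT4, also known as RARRES3, by 5.51 ± 0.17. The RNA sensor DHX58 rose by 4.49 ± 0.19, BAMBI, a decoy receptor of the TGF-beta family, by 4.35 ± 0.17, ANGPTL4, an inhibitor of lipoprotein lipase, by 4.33 ± 0.20, and the basal keratin KRT5 by 4.33 ± 0.17. The complement factor CFB was at least 131-fold higher, LCA5L at least 120.4-fold and the secreted protease KLK8 at least 105.3-fold. None of these 3 was well above background on either MKN-45 array.

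Metallothioneins, which bind zinc and copper, rose in MKN-45-P. MT1M was at least 7.30-fold higher, MT1E rose by 3.34 ± 0.18 on the log2 scale, MT1L by 2.93 ± 0.17 and MT1G by 2.70 ± 0.17. Of 13 tested genes 11 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.89e-10; adjusted p = 0.9995 with an estimated correlation). The family's sequences are close to each other, so that 1 probe can report several members.

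Genes of the response to amino acid shortage and unfolded proteins rose. VLDLR, a lipoprotein receptor well above background on only 1 MKN-45 array, rose by about 3.95 ± 0.25 (SE) on the log2 scale, CTH, an enzyme of cysteine synthesis, by 2.55 ± 0.18, the transcription factor ATF3 by 2.34 ± 0.18 and TRIB3, a pseudokinase induced by ATF4, by 2.31 ± 0.17. Of the 34 genes 22 rose and 0 fell, or 23 and 1 adjusted over the list alone (camera adjusted p = 1.41e-07; adjusted p = 0.9995 with an estimated correlation), and 7 rose without MKN-45-P replicate 1 and 6 without replicate 2. The chaperones of the endoplasmic reticulum HSPA5 (log2 fold change 0.16 ± 0.18) and HSP90B1 (0.08 ± 0.19), and HERPUD1 (-0.05 ± 0.17), members named after their values were seen, did not pass the test.

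Hypoxia-induced genes rose as well. The aldolase gene ALDOC rose by 4.40 ± 0.22 (SE) on the log2 scale, with its MKN-45 level from replicate 2 alone, since its spot on replicate 1 was marked as an outlier; with such spots kept the log2 fold change was 3.16. ANGPTL4 rose by 4.33 ± 0.20, the secreted hormone gene STC2 by 1.77 ± 0.18 (a second probe gave 0.79) and the angiogenic factor VEGFA by 1.73 ± 0.17. Of 32 tested genes 18 rose and 0 fell, or 20 and 0 adjusted over the list alone (camera adjusted p = 7.80e-05; adjusted p = 0.9995 with an estimated correlation). The calls of STC2 and VEGFA were lost without MKN-45-P replicate 1 (adjusted p = 0.0671 and 0.0980) and without MKN-45-P replicate 2 (0.0590 and 0.0542), and in either case 2 genes of the list rose.

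Signalling proteins and receptors of inflammation rose more often than they fell. Of 26 tested chemokines, cytokines and their receptors, 15 rose and 3 fell, or 17 and 4 adjusted over the list alone (camera adjusted p = 2.53e-04, and 0.9995 with an estimated correlation). Camera called this list in 13 of 15 other settings of the processing. TNFSF10, the death ligand TRAIL, rose by 5.48 ± 0.20 on the log2 scale, IL32 by 3.52 ± 0.19 and IL15 by 2.93 ± 0.20, all approximate since each was well above background on only 1 MKN-45 array, and IL7 was at least 1.86-fold higher. The 3 that fell, named after their values were seen, were TGFB3 (log2 fold change -1.29), TGFB1 (-1.01) and IL18 (-0.91). Of 23 NF-kappaB targets 12 rose and 4 fell, or 14 and 4 adjusted over the list alone. Among them were ICAM1, an adhesion molecule for leukocytes, at least 8.47-fold higher, IRF1, which rose by 2.82 ± 0.17 on the log2 scale, and LTB, with a log2 fold change of -2.50 ± 0.22. This list's camera adjusted p was 0.0230, and 0.9995 with an estimated correlation. It was called in 11 of 15 other settings, and not without MKN-45 replicate 2. Without MKN-45-P replicate 1, 6 cytokine genes rose and 0 fell, and without replicate 2, 7 and 0, while 5 NF-kappaB targets rose and 1 fell without either, and the calls of TGFB3, TGFB1 and IL18 were lost.

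Several genes of the cell surface, the matrix and secreted proteases rose. KLK6, well above background on only 1 MKN-45 array, rose by about 4.68 ± 0.17 on the log2 scale and KLK10 by 3.82 ± 0.18, both kallikrein proteases, and the membrane protease TMPRSS3 was at least 4.74-fold higher. Of 30 tested proteases and inhibitors 16 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00158, and 0.179 without MKN-45 replicate 2; adjusted p = 0.9995 with an estimated correlation). The 4 that fell, named after their values were seen, were the trypsin inhibitor SPINK1 (at least 5.30-fold), the collagenase MMP1 (at least 2.83-fold), PLAU (log2 fold change -1.09) and SERPINB5 (-0.85). FBLN1, a matrix glycoprotein, was at least 42.9-fold higher, the collagen gene COL12A1 rose by 3.17 ± 0.18 on the log2 scale, and the collagen genes COL6A2 and COL1A1 were at least 2.35-fold and 1.61-fold higher. Of 21 extracellular matrix genes 11 rose and 3 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0489, and 0.9995 with an estimated correlation). This call held in only 8 of 15 other settings. Leaving out MKN-45 replicate 1 or replicate 2 was among the settings that lost it. Of 31 integrins and adhesion receptors 12 rose and 3 fell, or 13 and 3 adjusted over the list alone, with ALCAM at least 2.27-fold, ITGB2 at least 1.46-fold and LGALS1 2.27 ± 0.17 higher on the log2 scale (camera adjusted p = 0.0343, and 0.179 without MKN-45 replicate 2; adjusted p = 0.9995 with an estimated correlation). The falls were CD44 (log2 fold change -1.13) and, named after their values were seen, CD24 (-1.60) and LGALS4 (-0.71), and those of the matrix genes, likewise, LUM (-1.80, well above background on only 1 MKN-45-P array), COL17A1 (-0.91) and LAMB1 (-0.60). With an MKN-45-P array left out, 8 proteases, 4 matrix genes and 5 or 6 adhesion receptors rose, and all calls of falling genes given here were lost except those of SPINK1, of MMP1 without replicate 2 and of LUM without replicate 2. Without MKN-45 replicate 1, 6 matrix genes and 5 adhesion receptors fell, and without MKN-45 replicate 2, 6 adhesion receptors.

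Among TGF-beta and BMP targets, INHBB, an activin subunit, rose by 5.93 ± 0.18 on the log2 scale, and the antagonists BAMBI and NOG rose by 4.35 ± 0.17 and 2.81 ± 0.17. INHBB and NOG were well above background on only 1 MKN-45 array, which makes their values approximate. Of 22 tested members 9 rose and 3 fell, with the same counts adjusted over the list alone. The 3 that fell, named after their values were seen, were PMEPA1 (log2 fold change -2.08), ID2 (-0.68) and SKIL (-0.58). The camera adjusted p was 0.0406, and 0.9995 with an estimated correlation. In 10 of 15 other settings the list was called, and not without MKN-45 replicate 2. Risen and fallen genes numbered 13 and 7 without MKN-45 replicate 1, 14 and 4 without MKN-45 replicate 2, and 4 and 1 without either MKN-45-P array, where the calls of ID2 and SKIL were lost.

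Genes lower in MKN-45-P included enzymes that clear alcohols and foreign compounds. GPC3, a heparan sulfate proteoglycan of the cell surface, had a log2 level of -4.09 ± 0.05 (SD, n = 2) in MKN-45-P and of 0.64 ± 0.14 (SD, n = 2) in MKN-45, a log2 fold change of -4.73 ± 0.17 (SE, adjusted p = 4.98e-07). The log2 fold change was -4.43 ± 0.17 for the secreted lectin gene REG4, -4.17 ± 0.18 for the Wnt antagonist DKK1, -3.93 ± 0.17 for the gap junction gene GJB1 and -3.61 ± 0.19 for FCGBP, which binds mucins. The calcium channel subunit CACNG6 (-4.66 ± 0.27) fell, as did the epidermal keratins KRT6B (-4.51 ± 0.18) and KRT6C (-3.33 ± 0.18), whose sequences are close. JAML, a junctional adhesion molecule (-3.47 ± 0.18), the ferroxidase HEPH (-3.23 ± 0.23) and the aldo-keto reductase AKR1B10 (-3.24 ± 0.19) were further falls. FBXL16 had a log2 fold change of -3.25 ± 1.02 (adjusted p = 0.0412), which was -1.13 without MKN-45 replicate 1 and -5.37 without MKN-45 replicate 2. Genes not well above background on either MKN-45-P array were the protease inhibitor SPINK5 (at least 58.9-fold lower), the esterase AADAC (51.1-fold), the alcohol dehydrogenases ADH1C (50.6-fold) and ADH1A (29.4-fold), the small GTPase RHOG (27.7-fold) and PGAP2 (25.03-fold).

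**Figure D2:**
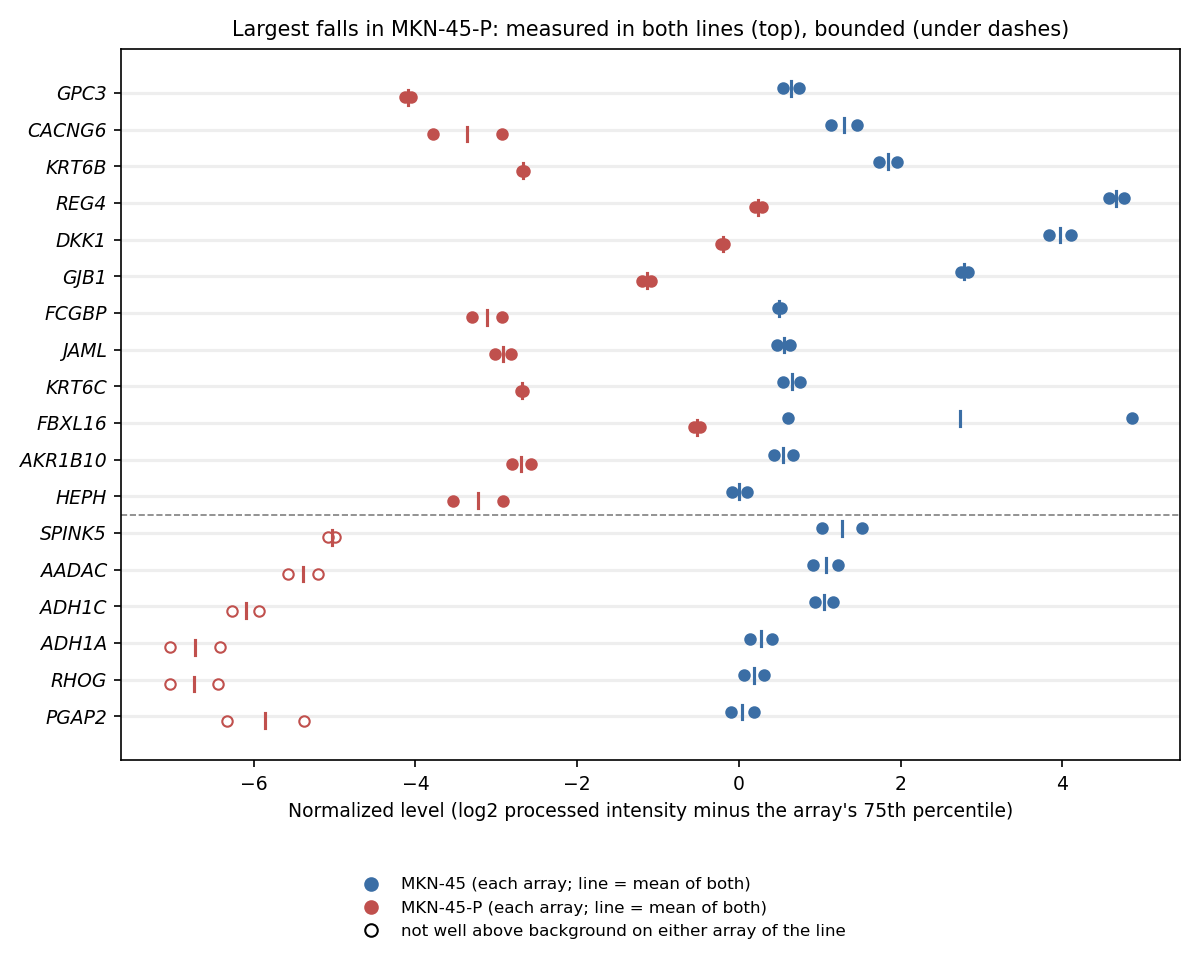
Normalized level of each gene (x axis, log2 processed intensity minus the array's 75th percentile) on the 2 arrays of each line, with a vertical line at each mean. The 12 upper genes were well above background on all 4 arrays; the 6 lower ones were not well above background on either MKN-45-P array (open points). The MKN-45 arrays differed for FBXL16, whose SE was 1.02.

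Of 45 tested NRF2 targets and genes of xenobiotic metabolism, 16 fell and 7 rose, or 17 and 8 adjusted over the list alone. Besides ADH1C, the retinaldehyde dehydrogenase ALDH1A1, well above background on only 1 MKN-45-P array, fell by about 4.77 ± 0.19 (SE) on the log2 scale, and UGT2B15, which glucuronidates steroids, was at least 6.90-fold lower, whereas the thymidine phosphorylase gene TYMP rose by 3.48 ± 0.18. The camera adjusted p was 7.88e-04, and 0.9995 with an estimated correlation. Calls of the NRF2 list held in 13 of 15 other settings, and not without MKN-45 replicate 1. Of 34 genes of cholesterol and lipid synthesis 14 fell and 3 rose, or 15 and 3 adjusted over the list alone (camera adjusted p = 1.71e-04; adjusted p = 0.9995 with an estimated correlation). The sterol demethylase CYP51A1 had a log2 fold change of -2.02 ± 0.22, the desaturase FADS2 of -1.34 ± 0.18 and the lanosterol synthase LSS of -1.29 ± 0.17, with other LSS probes between -3.93 and -0.74. The 3 that rose were SREBF2 (log2 fold change 1.26 ± 0.18) and, named after their values were seen, SREBF1 (0.95 ± 0.17) and ACACA (0.92 ± 0.18). The first 2 encode the transcription factors of this pathway. SREBF2 lies on chromosome 22, whose 303 tested genes had a median log2 fold change of 0.75, so its rise may not be particular to the pathway. Of 21 stem cell markers 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 7.13e-04; adjusted p = 0.9995 with an estimated correlation). ALDH1A1 was 1 of them, and the others included the transcription factor SOX2 (log2 fold change -3.05 ± 0.19), LRIG1 (-1.29 ± 0.18) and ASCL2 (-1.23 ± 0.19). The member that rose, KLF4 (0.60 ± 0.18), was named after its value was seen. Without MKN-45-P replicate 1 and without replicate 2, the adjusted p was 0.355 and 0.269 for FADS2, 0.386 and 0.326 for LSS, 0.362 and 0.3998 for SREBF2, 0.308 and 0.391 for LRIG1 and 0.530 and 0.319 for ASCL2, and the calls of SREBF1, ACACA and KLF4 were lost too. In these 2 settings 7 and 8 NRF2 targets fell and 2 rose, 1 cholesterol gene fell and 0 rose, and 2 stem cell markers fell and 0 rose. Without MKN-45 replicate 1, 25 cholesterol genes fell and 3 stem cell markers rose, and without MKN-45 replicate 2, 12 NRF2 targets and 4 stem cell markers rose.

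**Figure D3:**
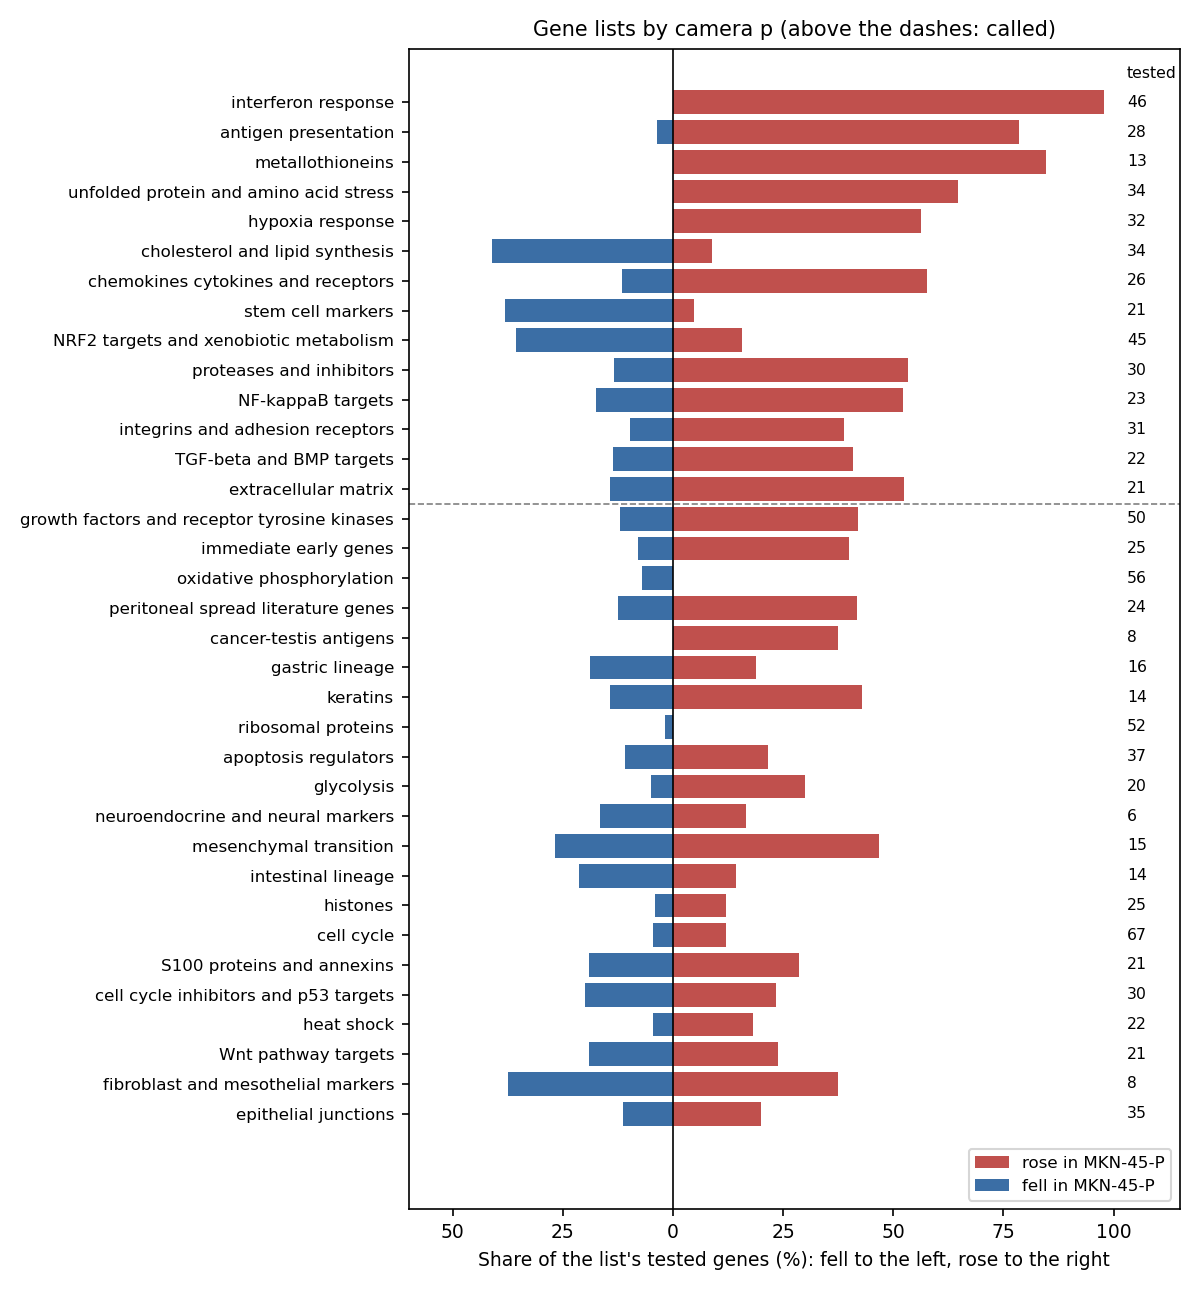
Share of each list's tested genes that rose (right, red) or fell (left, blue) in MKN-45-P at an adjusted p under 0.05 (x axis, percent), for the 35 lists tested, ordered by camera p, with the number of genes tested at the right. The 14 lists above the dashed line were called; in the interferon response 45 of 46 genes rose.

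Lists of tissue type were not called by camera in the main fit. Of 35 epithelial junction genes 7 rose and 4 fell (camera adjusted p = 0.997), also adjusted over the list alone. The claudin gene CLDN2 fell by 3.28 ± 0.17 on the log2 scale, and the E-cadherin gene CDH1 had a log2 fold change of 0.46 ± 0.18 (adjusted p = 0.0776). Of 15 mesenchymal transition genes 7 rose and 4 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.578, and 0.0443 with probes well above background on all 4 arrays). The transcription factor TWIST1 rose by 2.17 ± 0.18, MYL9 was at least 2.06-fold higher, and WNT5B had a log2 fold change of -3.70 ± 0.18. TNC, a matrix protein, had a log2 fold change of 2.78 ± 0.78, which was 1.17 without MKN-45 replicate 1 and 4.39 without MKN-45 replicate 2. Of 16 gastric lineage genes 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.1996), among them VSIG1, at least 17.9-fold lower, and the trefoil peptide TFF2, up by 2.23 ± 0.18. Of 14 intestinal lineage genes 2 rose and 3 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.578). This list was called down without MKN-45-P replicate 1 (adjusted p = 0.0272), with median centring (0.0360) and with normexp (0.0378). GPA33, an intestinal surface antigen not well above background on either MKN-45-P array, had a log2 fold change of -6.56 ± 1.57 (-3.28 without MKN-45 replicate 1 and -9.84 without MKN-45 replicate 2), so that no lower bound is given. CLDN2 and WNT5B were well above background on only 1 MKN-45-P array, and TNC and TFF2 on only 1 MKN-45 array, which makes their values approximate. Of 24 genes linked to peritoneal spread 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.107). Of 14 keratins 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.206). Of 8 cancer-testis antigens 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.115, fry adjusted p = 0.0325), with CSAG1 at least 4.22-fold higher. Of 8 fibroblast and mesothelial markers 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.972), with the mesothelial WT1 at a log2 fold change of -1.74 ± 0.17 (adjusted p = 0.0817 without MKN-45-P replicate 1 and 0.0641 without replicate 2). With 1 array left out, risen genes ranged from 0 to 16 and fallen ones from 1 to 7 among junction genes, from 3 to 9 and 1 to 4 among mesenchymal genes, from 1 to 5 and 2 to 7 among gastric genes and from 0 to 5 and 2 to 4 among intestinal genes. The ranges were 2 to 14 and 1 to 5 for peritoneal spread, 1 to 10 and 1 to 2 for keratins, 2 to 5 and 0 to 2 for cancer-testis antigens and 2 to 3 and 0 to 3 for fibroblast and mesothelial markers, with the lowest counts without an MKN-45-P array.

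Lists of growth and basic cell functions were not called either. Of 67 cell cycle genes 8 rose and 3 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.785), with the phosphatase gene CDC25B up by 1.08 ± 0.17 on the log2 scale (adjusted p = 0.592 without MKN-45-P replicate 1 and 0.568 without replicate 2). Cell cycle genes that rose and fell numbered 12 and 13 without MKN-45 replicate 1, 34 and 3 without MKN-45 replicate 2, and 0 and 0 without either MKN-45-P array. Of 50 growth factors and receptor tyrosine kinases 21 rose and 6 fell, or 21 and 8 adjusted over the list alone (camera adjusted p = 0.0575). The adjusted p was 0.0234 without MKN-45 replicate 1, 0.0462 with probes well above background on all 4 arrays and 0.0478 with the mean of a gene's probes. Of 25 immediate early genes 10 rose and 2 fell, also adjusted over the list alone (0.0867), and the adjusted p was 0.0274 without MKN-45 replicate 1, 0.0473 with quantile normalization and 0.00690 without a filter on dim probes. Of 37 apoptosis regulators 8 rose and 4 fell, or 10 and 4 adjusted over the list alone (0.228), and of 20 glycolysis genes 6 rose and 1 fell, or 7 and 1 (0.443). Of 30 cell cycle inhibitors and p53 targets 7 rose and 6 fell, or 9 and 6 adjusted over the list alone (0.972), and of 21 Wnt targets 5 rose and 4 fell, or 6 and 4 (0.972). Of 25 histone genes 3 rose and 1 fell, or 1 and 0 adjusted over the list alone (0.785). Of 22 heat shock genes 4 rose and 1 fell (0.972), of 21 S100 proteins and annexins 6 rose and 4 fell (0.808) and of 6 neuroendocrine markers 1 rose and 1 fell (0.511), with the same counts adjusted over each list alone. Of 56 oxidative phosphorylation genes 0 rose and 4 fell, or 0 and 2 adjusted over the list alone (0.0928). Of 52 ribosomal protein genes 0 rose and 1 fell, or 0 and 0 adjusted over the list alone (0.206). The oxidative phosphorylation and ribosomal lists were called down without MKN-45 replicate 1 (adjusted p = 0.00202 and 3.36e-05) and with quantile normalization of all 4 arrays (0.00602 and 0.00205). Without MKN-45 replicate 1, 24 and 21 of their genes fell, and without MKN-45 replicate 2, 10 and 17 rose, with the ribosomal median at 0.20. With 1 array left out, risen genes ranged from 2 to 32 and fallen ones from 0 to 11 among growth factors, from 2 to 18 and 0 to 4 among immediate early genes, from 3 to 19 and 0 to 9 among apoptosis regulators, from 1 to 11 and 0 to 3 in glycolysis and from 0 to 12 and 0 to 8 among p53 targets. The ranges were 3 to 9 and 1 to 6 for Wnt targets, 1 to 13 and 0 to 4 for histones, 1 to 9 and 0 to 9 for heat shock, 2 to 14 and 2 to 6 for S100 proteins and annexins and 0 to 3 and 0 to 4 for neuroendocrine markers, with the lowest counts without an MKN-45-P array.

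Genes often studied in gastric cancer were given whatever their change. The receptor gene MET had log2 levels of 6.72 ± 0.09 in MKN-45-P and 6.50 ± 0.40 in MKN-45 (SD, n = 2), a log2 fold change of 0.22 ± 0.22 (SE, adjusted p = 0.493). The value for MET was -0.07 without MKN-45 replicate 1 and 0.50 without MKN-45 replicate 2. CD44, a hyaluronan receptor, fell by 1.13 ± 0.18 on the log2 scale (adjusted p = 0.00172), the receptor gene ERBB2 rose by 0.76 ± 0.19 (0.0140) and the proliferation marker MKI67 by 0.65 ± 0.17 (0.0211). Without MKN-45-P replicate 1 their adjusted p was 0.552, 0.934 and 1.000, and without replicate 2 it was 0.493, 1 and 1. GAPDH had a log2 fold change of 0.00 ± 0.19, of either sign across scalings.

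In total, 2251 genes were higher and 1330 lower in MKN-45-P in limma's moderated test at an adjusted p under 0.05, and 1111 and 473 of them had a fitted change of at least 2-fold, or 981 and 470 with genes under background at their bound. Among the called genes, 275 higher ones were not well above background on either MKN-45 array, and 50 lower ones on either MKN-45-P array. MKN-45 replicate 1 had 19540 probes well above background, against 22203 to 23670 on the other arrays. Dim genes thus entered the test more easily through MKN-45-P, which favours calls of higher genes. With probes well above background on all 4 arrays, 823 genes were higher and 671 lower. The excess of higher genes may therefore come in part from the filter. The 2 lines did not overlap in 68.5% of tested genes, against 33.3% by chance. The counts depended on the arrays: 2808 and 3382 genes were higher and lower without MKN-45 replicate 1, 4737 and 2052 without MKN-45 replicate 2, 505 and 214 without MKN-45-P replicate 1, and 521 and 221 without MKN-45-P replicate 2, where no change under 1.82 on the log2 scale was called. Without an MKN-45-P array the spread comes from the MKN-45 arrays alone, and smaller changes lost their call. Nearly all probes then shared a common variance, so a lost call marks a smaller change and not by itself an unsteady gene. The share of calls that were higher was 62.9% with scaling to the 75th percentile, 51.6% with median centring and 45.4% without MKN-45 replicate 1, and median centring moved the median log2 fold change of all genes from 0.05 to -0.05.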

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

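The report names genes only. Of 5060 tested probes with no gene symbol, 488 were at least 2-fold higher in MKN-45-P and 192 at least 2-fold lower. These shares are close to those of genes with a symbol, 1111 and 473 of 11740, so the counts show no separate signal. Such probes stand for expressed sequences that the gene table did not name.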

How the results depend on the processing

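Directions of the named genes held in most settings, and counts did not. Among the 150 genes that the naming rule picked, the direction was kept except that of GAPDH, with log2 fold changes of -0.0645 with quantile normalization, -0.10 with median centring and from -0.20 to 0.21 with 1 array left out, and that of MET, from -0.0655 to 0.50 with 1 array left out. Higher and lower genes numbered 1082 and 605 with normexp, 97 and 27 without a filter on dim probes (all of them at least 2-fold), 823 and 671 with probes well above background on all 4 arrays (585 at least 2-fold higher) and 1202 and 636 with the replicate block. The filter on all 4 arrays tests 10456 genes in place of 11740, too small a loss to account for its fewer calls. Its eBayes prior was worth 36772 degrees of freedom, against 6.86 in the main fit. With normexp the prior was worth 43907 and with the replicate block 21830. Without MKN-45-P replicate 1 and without replicate 2 it was worth 21842 and 21830. A prior so large gives nearly all probes a common variance, so calls there rest almost on the size of the change alone. How far this accounts for the fewer calls was not tested, and nor was the cause without a filter on dim probes. Over the settings that leave 1 array out, higher genes ranged from 505 to 4737, lower genes from 214 to 3382, genes at least 2-fold higher from 505 to 1357, genes at least 2-fold lower from 214 to 592 and called lists from 9 to 16. Of the 147 named genes that were called, 96 were called with any 1 array left out, and 50 lost the call without an MKN-45-P array. Called lists numbered 0 with an estimated correlation in camera (1 at an unadjusted p under 0.05) and 6 with fry, against 14. Fry called interferon response, antigen presentation, metallothioneins, cytokines, integrins and cancer-testis antigens, the last of which is not among the 14. Lists that fry did not call included unfolded protein and amino acid stress (adjusted p = 0.0671), hypoxia (0.0680), cholesterol and lipid synthesis (0.140) and stem cell markers (0.0766). The 7 lists called in all 15 other settings are interferon response, antigen presentation, metallothioneins, unfolded protein and amino acid stress, hypoxia, and, downwards, cholesterol and lipid synthesis and stem cell markers, while proteases were called in 14, cytokines and NRF2 targets in 13, NF-kappaB targets in 11, TGF-beta targets and integrins in 10 and the matrix in 8. The replicate numbers do not pair the samples by any label, and the deviations of same-numbered arrays had a correlation of 0.12 over probes, with 2 groups of 2. With the block the intestinal lineage list was called down (adjusted p = 0.0365), and no other list's call changed. The 2 other splits of the 4 arrays into pairs called 0 genes each in limma (14 and 17 at an unadjusted p under 0.05), against 3581. Each of them joins an MKN-45 array with an MKN-45-P array, so the difference between the lines enters the spread and holds calls down. The counts of 0 are therefore no measure of false calls among the 3581, and 3 splits are too few to reach a share under 0.05.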

Other observations

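The tests on single genes and lists in this part were chosen after the comparison had been seen. Complement genes rose in MKN-45-P: of 14 tested members of a list written after the values were seen, 9 rose and 1 fell (camera adjusted p = 6.32e-09, and 0.0971 with an estimated correlation). C2 was at least 13.1-fold higher and the C1 inhibitor SERPING1 at least 9.58-fold higher, and C1R and C1S rose by 3.88 ± 0.17 and 3.69 ± 0.22 (SE) on the log2 scale, approximate values since both were well above background on only 1 MKN-45 array. The membrane regulators CD46 (log2 fold change 0.01), CD55 (-0.01) and CD59 (-0.06) did not pass the test. Guanylate-binding proteins and sensors of nucleic acids followed, with 18 of 23 risen and 0 fallen (camera adjusted p = 5.01e-17, and 0.0971 with an estimated correlation): the DNA sensor IFI16 was at least 65.0-fold higher, GBP4 at least 20.8-fold, and STING1 rose by 3.46 ± 0.18. The 18 constitutive proteasome genes held no call (camera adjusted p = 0.786). The complement and sensor lists were drawn from the changed genes, and none of these lists is independent evidence.

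Enzymes that handle alcohols, steroids and retinoids or conjugate them fell together. Of 18 tested members of a list written after the values were seen, 14 fell and 2 rose (camera adjusted p = 5.01e-17, and 0.224 with an estimated correlation), and the median log2 fold change was -2.53. The sulfotransferase SULT1C2 was at least 6.56-fold lower, the bile acid enzyme BAAT at least 5.96-fold, and AKR1C3 fell by 2.25 ± 0.19 on the log2 scale, while CYP2J2 rose by 3.23 ± 0.21. Of 7 tested kallikreins 4 rose (camera adjusted p = 1.41e-05, and 0.224 with an estimated correlation): besides KLK8, KLK6 and KLK10, KLK1 rose by 2.76 ± 0.23, while KLK9 (0.27 ± 0.22), which lies among them, KLK14 (0.08 ± 0.20) and KLK3 (-0.32 ± 0.33) did not pass the test. CYP2J2, KLK6, KLK1 and KLK14 were well above background on only 1 MKN-45 array. The enzyme and kallikrein lists were both written after the values were seen and are no independent evidence either.

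Genes of chromosome 22 were higher in MKN-45-P almost throughout. Of 303 tested genes 192 rose and 4 fell, with a median log2 fold change of 0.75 against 0.05 over all genes. This lay above each of 10000 random lists matched on brightness, as did the smaller medians of chromosomes 1 (0.13) and 17 (0.25). The medians of chromosomes 7 (-0.04), 11 (-0.10), 14 (-0.32), 19 (-0.22) and 21 (-0.19) lay below every such list. Random lists take no account of neighbouring genes that shift together, so small medians also fell outside them. After regression on probe GC content and brightness the median of chromosome 22 stayed 0.66 above that of all genes, without MKN-45 replicate 1 it stayed 0.70 above, and 93.4% of its genes lay above 0, which argues against GC content, the aberrant array and a few strong genes. More copies of chromosome 22 in MKN-45-P than in MKN-45 are a candidate explanation: all 7 of its windows of 5 Mb were shifted, with medians of 0.56 in the lowest and of 0.75 to 0.86 in the others, the latter above the 0.58 that 3 copies against 2 would give. DNA was not measured, so this is a hypothesis, and the last 2 of these tests were chosen after the windows and shares had been seen.

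The interferon pattern was set against other sources. Leukocytes or endothelial cells in the MKN-45-P samples would bring their other transcripts, and only 1 of 27 listed markers, CD68, was well above background on both MKN-45-P arrays and at least 2-fold higher there; PTPRC and LAPTM5 were not well above background on both. The aberrant MKN-45 replicate 1 array does not carry the pattern, since 46 of the 46 interferon genes rose without it; both of these tests were chosen after the values were seen. Interferon made by the MKN-45-P cells themselves would need its transcripts, and 0 of the 16 interferon genes on the array were well above background on both MKN-45-P arrays, a test of RNA at harvest that was set before its values were seen. An infection or another difference of the MKN-45-P culture, or a lasting change in the pathway itself, may underlie the pattern, and the data cannot separate them: of 13 receptors and signalling genes 7 rose, among them IRF9 (2.75 ± 0.17), and 1, the receptor gene IFNAR1 (-0.87, a call lost without either MKN-45-P array), fell (camera adjusted p = 0.00289, and 0.374 with an estimated correlation).

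Neighbouring genes changed together in 11 pairs among 126 genes with a fitted change of at least 16-fold. With genes under background at their bound 78 genes are left, and C2, GLI2, IFI44L and SAMD9L, each in a separate pair, fall below 16-fold. In 10000 shuffles of the fitted changes the mean was 0.85 pairs (permutation p = 1.00e-04, the smallest they can give), which argues against chance placement. Most pairs are relatives, such as IFIT2 and IFIT3 or ADH1A and ADH1C, and leaving out pairs whose symbols share their first letters, the test set beforehand, left 5 pairs (permutation p = 0.00110). That rule missed the relatives MX1 with MX2 and C2 with CFB, and without these 3 pairs are left, a count with a permutation p of 0.0513, so that gene families may account for the excess. The 3 pairs are INHBB with GLI2 and NEU1 with SLC44A4, higher in MKN-45-P, and PGAP2 with RHOG, under background there, whose probes lie 1.104 kb apart on chromosome 11, from 3803928 to 3803987 and from 3805032 to 3805091 in the hg17 build, share 0 stretches of 15 bases, and sit between NUP98 (log2 fold change 0.29) and STIM1 (0.81); a small deletion in MKN-45-P is an untested way to lose both.

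Other stretches moved together too. The first 40 Mb of chromosome 2 held 143 tested genes with a median log2 fold change of 0.66, against -0.05 for the rest of the chromosome. On chromosome 6 the first 15 Mb had a median of -0.84 over 48 genes, and chromosome 14 had a median of -0.32 over 397 genes. These stretches were picked after the values had been seen.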
